A study of Mus musculus with 7 samples.

How the data were processed

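Whole-transcript microarray values of sorted splenic cDC1 were analysed for 3 WT and 4 KO arrays, with groups and replicate numbers taken from the sample titles. Cells came from tumor-bearing mice, total RNA was prepared with a micro-scale column kit, and RNA was amplified and labelled with a whole-transcript kit for Affymetrix arrays, per the labels' protocols. The authors deposited 1 table of 28846 probe sets by 7 arrays on a log2 scale, made with RMA and Affymetrix Expression Console 1.1 per the submitters' processing notes. RMA names background correction, quantile normalization and median polish; which arrays were normalized together is not given in the sources used here. The scale was read from the values, which lay between 3.68 and 14.28. Scanner files were not analysed here. Summarised values of this kind compress small signals toward the background, so differences of dim genes are understated, and the number of arrays, not a read depth, limits precision.

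The table held 22206 transcript probe sets and 6640 control probe sets. The platform annotation gave 1 gene symbol to 19572 transcript probe sets, several to 0, and listed no gene for 2634, which are unnamed here. All 19572 matched the reference gene table by gene identifier, and 0 symbols changed. Where several probe sets had the same symbol, the one with the highest mean over the 7 arrays was kept, which left 19505 genes and dropped 67 probe sets. No coordinates are given, since no genome build is named in the sources used here. All 7 value columns were matched to samples, and 0 were left unmapped.

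KO was compared with WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A difference is KO minus WT in log2 units. Gene lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, which asks whether members shift relative to the other genes. Adjustment was over the 36 lists, and camera with an estimated correlation and fry were run beside it. Fry asks whether a list's members move, on balance, in 1 direction or in either, without comparing them with other genes. Counts adjusted over the list alone use the members' limma p-values. Opa1 was also tested by an exact two-sided permutation over the 35 splits of 7 arrays into 3 and 4.

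The design, the alternatives, 37 gene lists with 1285 genes (1151 measured) and the rule for named genes were fixed before the data were examined. The rule named Opa1, then per direction the 12 genes with the largest difference among those past the threshold with no overlap between groups, filled up by smallest unadjusted p and given as values only, and up to 4 members of each list by unadjusted p. Provisional symbols were counted, not named. Further genes printed from the lists written later were chosen after their values were seen. Those lists, of melanocyte lineage genes, shared cDC1 markers, spleen resident CD8a cDC1 genes, pan-leukocyte genes, and fibroblast and endothelial markers, were written after values had been seen.

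The scripts were tested on simulated data for the KO against WT comparison, over 19505 genes with 200 changed. With the spread of the 4 KO arrays, 87% of changes of 1 log2 and 97% of changes of 2 log2 were called, with 9 false calls; with the residual spread of all 7 arrays, 69% and 97% were called, with 8 false calls. Of 3 lists shifted upward by 0.5 log2, 3 were recovered, and 0 of 31 lists without shifted genes were called higher. Calls of those lists as lower were not counted. The simulated noise was independent between genes, so this does not test the preset correlation on the real arrays. Both simulated groups had the same spread per gene, whereas on the real arrays WT varied more than KO (median SD 0.197 against 0.142). The shares called therefore need not hold there. On the real arrays Dct, at -4.13, was not called (limma, adjusted p = 0.223).

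Alternatives fixed beforehand were leaving out each array, the replicate number as a block, median centring, quantile normalization, a filter on dim probe sets (mean under the median of the transcript probe sets), trended and robust variance, array weights, every named probe set, a log2 difference of at least 1, another test per gene, an estimated correlation, fry and rank-based camera. Leaving out WT 1 and WT 2 together, the mean of the melanocyte list as a covariate, and an estimated correlation within 16 other alternatives, were added after the data had been seen. In the former the lone WT array is assumed to vary like the KO arrays.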

Results

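RNA abundance was measured in type 1 conventional dendritic cells (cDC1), the dendritic cell subset specialised in cross-presenting antigen to CD8 T cells, sorted from the spleens of C57BL/6 mice that carried B16-OVA tumors, a mouse melanoma line expressing ovalbumin. The labels give 3 wild-type arrays (WT) and 4 arrays from mice in which a Cre recombinase driven by CD11c acts on a floxed Opa1 gene (KO). OPA1 is the GTPase that fuses the inner mitochondrial membrane and holds the cristae in shape. The question was what the loss of Opa1 in CD11c-expressing cells does to the transcriptome of splenic cDC1. The labels do not say which arrays came from separate mice, so p-values measure only the spread between these arrays, which may be in part technical. Values were deposited on a log2 scale, and 19505 named genes were compared. The median of all 28846 rows was 7.87, 7.85 and 7.89 for WT 1 to 3, and 7.96, 7.86, 7.89 and 7.94 for KO 1 to 4. The number of arrays limits the precision of every comparison.

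Opa1, measured by probe set TC1600000387.mm.2, had a log2 value of 8.69 ± 0.51 (SD, n = 3) in WT and 7.47 ± 0.62 (SD, n = 4) in KO. The difference, KO minus WT, was -1.22 with a standard error of 0.363, and it did not pass correction over all genes (limma, adjusted p = 0.223). In an exact two-sided permutation test of Opa1 alone p was 0.114, with 2 of 35 splits as low, where the smallest p the design allows is 0.0571. The arrays labelled WT 1 to 3 read 8.14, 8.80 and 9.15, and those labelled KO 1 to 4 read 7.70, 7.10, 6.85 and 8.24. The array labelled KO 4 thus lay above the array labelled WT 1, while WT 2 and WT 3 lay above every KO array. WT 1 also differed in genes that mark cell types, as given below. Probes that lie outside the deleted part of the gene would not register the deletion, and their positions were not analysed here. Groups are therefore named throughout as the arrays are labelled.

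**Figure D1:**
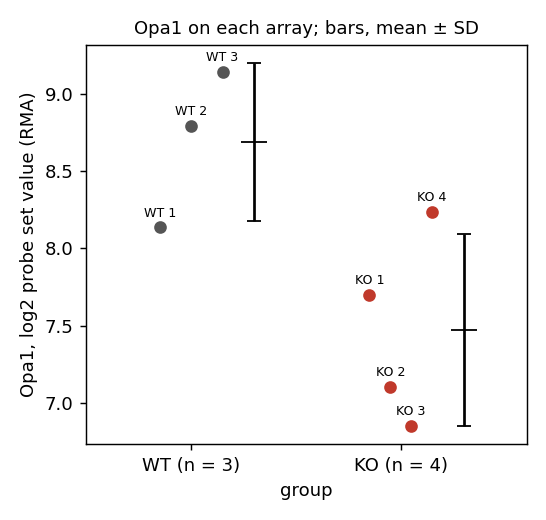
Log2 value of the Opa1 probe set (vertical axis) on each array, by labelled group (horizontal axis), with mean and SD as bars. The WT mean was 8.69 and the KO mean 7.47. The array labelled KO 4 (8.24) lay above the array labelled WT 1 (8.14), while WT 2 (8.80) and WT 3 (9.15) lay above every KO array.

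The arrays labelled WT 1 and WT 2 differed from the others in genes that mark cell types. Pmel, a melanosome structural protein, read 13.51 and 13.59 on the arrays labelled WT 1 and WT 2, 11.62 on WT 3, and 9.13 ± 0.82 (SD, n = 4) in KO. Tyr, the rate-limiting enzyme of melanin synthesis, read 11.96, 12.31 and 8.80 on WT 1 to 3, and between 6.20 and 7.15 on the KO arrays. Of a list of 27 melanocyte lineage genes, written after such genes had been seen to lead the differences, 26 were measured, and all 26 had a lower mean in KO, 19 of them with no overlap between the groups. The mean of that list, relative to the KO mean, was 3.38 on WT 1, 3.74 on WT 2 and 0.92 on WT 3, against 0.23, 0.09, -0.02 and -0.30 on KO 1 to 4. Cd8a, which marks the resident cDC1 of spleen, read 7.89 and 6.96 on the arrays labelled WT 1 and WT 2, 12.11 on WT 3 and 12.01 ± 0.08 (SD, n = 4) in KO. Xcr1, the chemokine receptor of cDC1, read 12.12 on WT 1, 7.97 on WT 2, 12.76 on WT 3 and 12.70 to 12.79 on the KO arrays. Across genes, which are not independent replicates, the arrays labelled WT 1 and WT 2 correlated at r = 0.982 with each other and at 0.924 to 0.954 with the other 5, which correlated among themselves at 0.988 to 0.993.

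**Figure D2:**
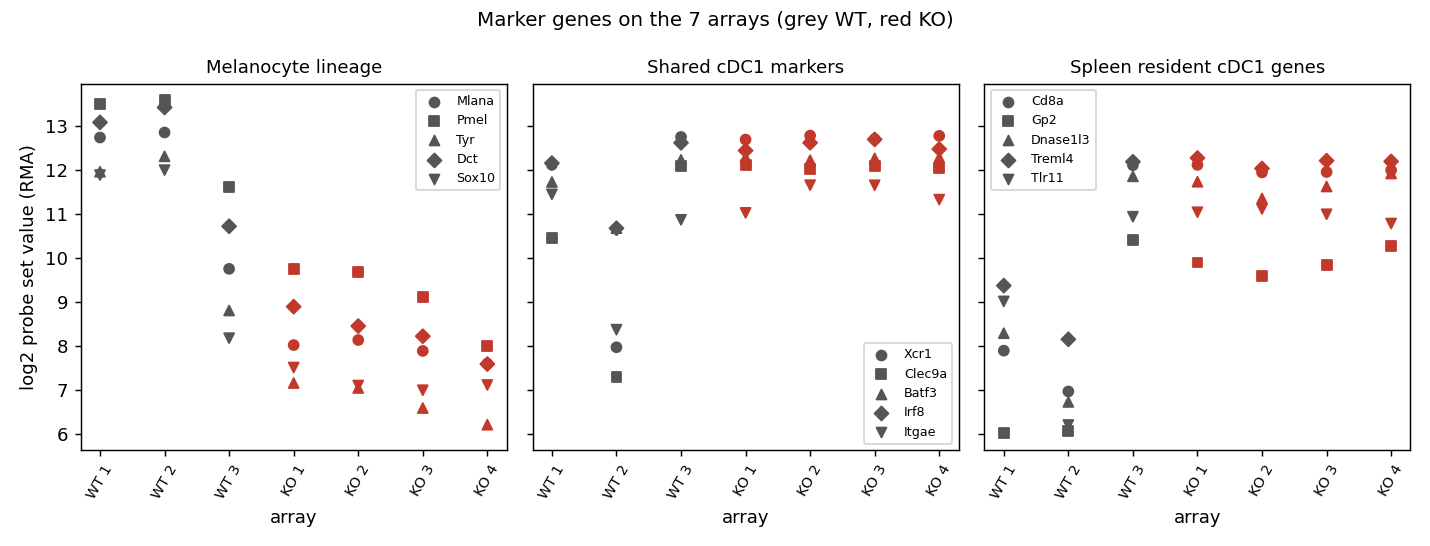
Log2 values (vertical axis) of 5 genes in each of 3 sets of markers on the 7 arrays (horizontal axis; grey WT, red KO; 1 point per gene and array); the 3 sets were written after some values had been seen. Melanocyte genes were highest on the arrays labelled WT 1 and WT 2, as for Pmel at 13.51 and 13.59, and Cd8a was lowest there, at 7.89 and 6.96.

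No gene of the 19505 passed the adjusted threshold of 0.05 between KO and WT in limma, where the smallest adjusted p was 0.223. At an unadjusted p under 0.05 there were 3820 genes, 1752 higher and 2068 lower in KO, against 975 expected by chance; after each array was centred on its median the split was 2632 higher and 1770 lower. In 1532 genes all KO values lay above all WT values and in 1155 all lay below, together 13.8% of genes against 5.71% by chance. Without the array labelled WT 3, 4931 genes passed, 2230 higher and 2701 lower in KO. Without the arrays labelled WT 1 and WT 2, left out together after the data had been seen, 0 genes passed (1154 at an unadjusted p under 0.05).

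As none passed, genes were named by their unadjusted p and are given as values. Among those lower in KO, Mybl1, a transcription factor of the MYB family, read 9.07 ± 0.25 (SD, n = 3) in WT and 7.98 ± 0.10 (SD, n = 4) in KO, a difference of -1.10. Pcgf5, a component of a Polycomb repressive complex, read 10.38 ± 0.16 in WT and 9.60 ± 0.06 in KO. Rad51c, which acts in homologous recombination, read 7.89 ± 0.12 and 7.18 ± 0.10, and Inpp5a, an inositol phosphatase, 9.82 ± 0.17 and 8.81 ± 0.25. For these 4 genes, as for all 12 named on the lower side by smallest p, the 3 WT arrays lay above every KO array. Mybl1 on WT 1 to 3 was 9.26, 9.17 and 8.79, and Inpp5a was 9.70, 10.01 and 9.74. Rab20, a small GTPase, differed by -1.12 and Ttc21b, a component of intraflagellar transport, by -1.19. Mybl1, Pcgf5, Rad51c and Ttc21b were also lower on WT 3 than on WT 1 and WT 2, while for Inpp5a and Rab20 WT 1 was the lowest WT array. The other 6 genes named on the lower side had differences of -3.31 to -4.86 and were higher on the arrays labelled WT 1 and WT 2 than on WT 3, by more. Those 6 were Dct, Pmel and Tyrp1, which belong to the melanocyte list, and Cpe, Cck and Ptgds, which encode a carboxypeptidase, the hormone cholecystokinin and a prostaglandin synthase. Ptgds read 12.88, 12.91 and 9.24 on WT 1 to 3 and 6.82 ± 0.36 (SD, n = 4) in KO.

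Among the genes higher in KO, Cxcr6, a chemokine receptor for CXCL16, read 6.74 ± 0.26 (SD, n = 3) in WT and 7.77 ± 0.18 (SD, n = 4) in KO, a difference of 1.03. Its WT values were 6.46, 6.78 and 6.98 and its KO values 7.99, 7.58, 7.84 and 7.67. Abhd1 differed by 0.80, Ankrd61 by 0.72, Oc90 by 0.63, Mlh3, a mismatch repair gene, by 0.62, Trpc1, a cation channel, by 0.60 and Tex14 by 0.60. The other 5, Cyp2ab1, Psg20, Tcl1b4, Rnf113a1 and Tgm4, differed by 0.46 to 0.57. Negative control probe sets had medians of 6.19 to 6.88 on the 7 arrays, and Tex14, at 5.53 ± 0.21 in WT and 6.13 ± 0.07 in KO, did not exceed them. Psg20 lay within that range on all 3 WT arrays, and Cxcr6, Ankrd61 and Oc90 did on at least 1 WT array. The control medians averaged 6.39 in WT and 6.73 in KO, so background may make up part of these differences.

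Of 37 gene lists written before the data were examined, 36 had enough measured members, and 23 were called relative to the other genes by camera with a preset correlation, 3 higher and 20 lower in KO. With an estimated correlation 0 were called, with adjusted p between 0.431 and 0.528 for those 23, and fry called 0 for a shift in one direction (smallest adjusted p 0.177) or in either (0.103). Without the arrays labelled WT 1 and WT 2, 14 lists were called by camera with the preset correlation, all lower in KO, 10 of them among the 23, and 0 with an estimated correlation. The 4 gained were cDC2, plasmacytoid, T and NK, and immediate early and heat shock genes. That setting compares 1 WT array with the KO arrays, so its calls, here and below, rest on WT 3 alone. WT 3 itself stood 0.92 above the KO mean on the melanocyte list. KO 2 and KO 4, each set alone against WT 3 and the other KO arrays, gave 15 called lists each, in mixed directions. A fit with the mean of the melanocyte list as a covariate was also added after the data had been seen. That list was written after its genes had been seen to lead the differences, and its mean correlated with the KO label at r = -0.847. Group differences in that fit are extrapolated and are not read as measured differences, so they are given only here and with the processing alternatives. It called 14 lists, and 16 of 36 lists changed direction. Of the 23 calls 4 were kept (interferon gamma, NF-kB, dendritic cell maturation, and monocytes and macrophages). A further 17 were lost, and 2 were called the opposite way, glycolysis and hypoxia higher and cDC1 identity lower in KO. The 8 gained, all lower, were the unfolded protein response, immediate early and heat shock genes, the cytosolic ribosome, MHC class I, cDC2, plasmacytoid, B and plasma, and T and NK cells. An estimated correlation, combined after the data had been seen with each of 16 alternatives to the chosen setting, called 0 lists in every one (smallest adjusted p 0.242). Each call gained under an alternative below therefore depended on the preset correlation. No list had a member past the threshold over all genes; counts adjusted over the list alone are given below.

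Genes of cholesterol biosynthesis and their regulator SREBP2 were lower in KO by a mean of -0.98, with 19 of 19 measured members lower and 14 past the threshold adjusted over the list alone (camera adjusted p = 6.3e-13; adjusted p = 0.431 with an estimated correlation). Sqle, squalene epoxidase, read 9.60 ± 0.86 (SD, n = 3) in WT and 7.84 ± 0.26 (SD, n = 4) in KO, Idi1 8.06 ± 0.82 and 6.26 ± 0.31, and Cyp51 10.36 ± 0.74 and 8.88 ± 0.19. The mean of that list relative to the KO mean was 1.37 on WT 1, 1.26 on WT 2 and 0.32 on WT 3. Genes of glycolysis and the hypoxia response had a mean of -0.90, with 33 of 33 lower and 2 past adjusted over the list alone (camera adjusted p = 2.87e-14; adjusted p = 0.435 with an estimated correlation). The list mean was 1.04 on WT 1, 1.54 on WT 2 and 0.11 on WT 3. Vegfa, a hypoxia-induced growth factor, read 12.04 and 12.17 on the arrays labelled WT 1 and WT 2, 9.51 on WT 3 and 8.56 ± 0.20 (SD, n = 4) in KO. Kdm3a, a histone demethylase, read 10.77 ± 0.39 in WT and 9.91 ± 0.03 in KO. For antioxidant targets of NRF2 the mean was -0.42, with 17 of 27 lower and 0 past adjusted over the list alone (camera adjusted p = 0.00459; adjusted p = 0.431 with an estimated correlation). For it WT 1 to 3 stood at 0.52, 0.61 and 0.12. Me1, malic enzyme, read 10.36, 10.84 and 6.71 on WT 1 to 3 and 6.12 ± 0.25 (SD, n = 4) in KO. All 3 lists were still called lower in KO by camera without WT 1 and WT 2, cholesterol at -0.32 (adjusted p = 2.44e-06), glycolysis and hypoxia at -0.11 (0.0253) and NRF2 at -0.12 (0.0493). With an estimated correlation adjusted p was 0.459 for each. The NRF2 call was lost with the dim filter (-0.28, camera adjusted p = 0.091).

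Of the lists of mitochondrial function, 8 were called lower in KO in the chosen setting. All 8 calls were lost without the arrays labelled WT 1 and WT 2 (camera adjusted p = 0.0624 for complex I and 0.11 to 0.32 for the others). The list of complex I had a mean of -0.16, with 34 of 47 members lower, and 1, Ndufab1, past adjusted over the list alone (camera adjusted p = 0.000241; adjusted p = 0.469 with an estimated correlation). Ndufab1, the mitochondrial acyl carrier protein, read 10.36 ± 0.33 (SD, n = 3) in WT and 9.43 ± 0.16 (SD, n = 4) in KO. The means were -0.20 for complexes II and III (18 of 23 lower, camera adjusted p = 0.000697), -0.15 for complex IV (23 of 29, 0.000928), -0.20 for ATP synthase (16 of 19, 0.000697) and -0.11 for the mitochondrial ribosome (49 of 75, 0.000928). With an estimated correlation adjusted p was 0.469 for each of these 4 lists, and 0 members passed adjusted over the list alone. Mitochondrial dynamics and cristae, the function that OPA1 serves, had a mean of -0.24, with 27 of 37 lower and 0 past adjusted over the list alone (camera adjusted p = 0.000187; adjusted p = 0.467 with an estimated correlation). In that list Chchd10, a protein of the intermembrane space, read 12.26, 12.42 and 9.46 on WT 1 to 3 and 9.12 ± 0.13 (SD, n = 4) in KO. The list of the TCA cycle had a mean of -0.19 (17 of 22 lower, camera adjusted p = 0.00356; adjusted p = 0.435 with an estimated correlation). That of mitochondrial chaperones, proteases and import had a mean of -0.10 (26 of 38 lower, 0.0114; adjusted p = 0.469 with an estimated correlation). On WT 3 the list means of these 8 lists were 0.03 to 0.06 above the KO mean, while on WT 2 they were 0.17 to 0.38 above it. The call of chaperones, proteases and import was also lost without WT 2 alone (-0.05, 0.138) and without WT 3 alone (-0.13, 0.0519). It was lost too with quantile normalization (-0.05, camera adjusted p = 0.101), the dim filter (-0.10, 0.091) and array weights (-0.08, 0.132), and that of the TCA cycle with the dim filter (-0.18, 0.0639). Fatty acid oxidation (mean -0.09, camera adjusted p = 0.327), mitochondrial genome maintenance and biogenesis (-0.09, 0.532) and NAD metabolism (-0.04, 0.447) were not called; in the latter pair the median was above 0 (0.01 and 0.03). Within the list of genome maintenance Ppargc1a, a coactivator of mitochondrial biogenesis, read 11.71, 12.02 and 7.97 on WT 1 to 3 and 7.30 ± 0.08 (SD, n = 4) in KO. Of the mitochondrial DNA encoded genes 0 were measured by a named probe set.

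The list of the type I interferon response had a mean of -0.91, with 42 of 47 members lower and 23 past adjusted over the list alone (camera adjusted p = 2.87e-14; adjusted p = 0.431 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I, read 10.97, 11.30 and 8.01 on WT 1 to 3 and 6.93 ± 0.72 (SD, n = 4) in KO. Ifit3, an interferon-induced antiviral gene, read 8.62 ± 0.82 in WT and 7.21 ± 0.34 in KO. The list mean was 1.07 on WT 1, 1.44 on WT 2 and 0.22 on WT 3, and without WT 1 and WT 2 it was still called lower in KO (-0.22, camera adjusted p = 1.96e-06; adjusted p = 0.459 with an estimated correlation). Genes induced by interferon gamma had a mean of -0.48, with 16 of 24 lower and 7 lower and 1 higher past adjusted over the list alone (camera adjusted p = 0.000928; adjusted p = 0.431 with an estimated correlation). Its list mean was 0.50, 0.62 and 0.32 on WT 1 to 3. The list of dendritic cell maturation and co-stimulation had a mean of -0.60, with 31 of 38 lower and 12 past adjusted over the list alone (camera adjusted p = 2.32e-09; adjusted p = 0.431 with an estimated correlation). In it Ccl22, a chemokine of mature dendritic cells, read 11.79, 11.47 and 10.21 on WT 1 to 3 and 9.34, 9.02, 8.86 and 10.14 on KO 1 to 4. Tnfsf4, the OX40 ligand, read 8.19 ± 0.71 (SD, n = 3) in WT and 6.84 ± 0.23 (SD, n = 4) in KO. Its list mean was 0.78 on WT 1, 0.59 on WT 2 and 0.44 on WT 3, where the KO arrays ranged from -0.34 to 0.36. Genes of NF-kB and inflammation had a mean of -0.21, with 28 of 42 lower and 0 past adjusted over the list alone (camera adjusted p = 0.00325; adjusted p = 0.469 with an estimated correlation). Its list mean was 0.03, 0.31 and 0.29 on WT 1 to 3, and the cytokine gene Il1b read 13.12 ± 0.15 in WT and 12.77 ± 0.14 in KO. When WT 1 and WT 2 were left out, the calls of the interferon gamma (-0.32, camera adjusted p = 0.00019), maturation (-0.44, 2.52e-11) and NF-kB lists (-0.29, 3.39e-09) were kept, with adjusted p = 0.459 for each with an estimated correlation. The call of the NF-kB list was lost without WT 3 (-0.17, camera adjusted p = 0.288), with the dim filter (-0.17, 0.0873) and with array weights (-0.12, 0.142).

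The list of the cell cycle had a mean of -0.51, with 46 of 50 lower and 13 past adjusted over the list alone (camera adjusted p = 5.77e-14; adjusted p = 0.431 with an estimated correlation). Kif11, a mitotic kinesin, read 9.28 ± 0.20 (SD, n = 3) in WT and 8.65 ± 0.14 (SD, n = 4) in KO, and Bub1, a spindle checkpoint kinase, 9.28 ± 0.74 and 7.93 ± 0.09. The list mean was 0.78 on WT 1, 0.66 on WT 2 and 0.10 on WT 3, and without WT 1 and WT 2 it was still called lower in KO (-0.10, camera adjusted p = 0.00123; adjusted p = 0.654 with an estimated correlation). The list of lysosome and TFEB targets had a mean of -0.49, with 34 of 46 lower and 4 past adjusted over the list alone (camera adjusted p = 2.45e-06; adjusted p = 0.431 with an estimated correlation). On this list WT 1 to 3 stood at 0.49, 0.79 and 0.18. Its members Gpnmb and Mitf belong to the melanocyte list too, and Gpnmb read 12.38, 12.63 and 9.18 on WT 1 to 3 against 7.32 ± 0.17 (SD, n = 4) in KO. That call was kept without WT 1 and WT 2 (-0.18, camera adjusted p = 9.06e-05; adjusted p = 0.459 with an estimated correlation). Targets of p53 had a mean of -0.24 (19 of 29 lower, 1 past adjusted over the list alone, camera adjusted p = 0.0133; adjusted p = 0.431 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, read 12.64 ± 0.69 and 11.17 ± 0.30. Targets of ATF4 and the integrated stress response, which mitochondrial damage can engage, had a mean of -0.18 (28 of 45 lower, 1 past adjusted over the list alone, camera adjusted p = 0.024; adjusted p = 0.469 with an estimated correlation). On WT 1 to 3 the p53 list stood at 0.21, 0.39 and 0.13 and the ATF4 list at 0.22, 0.33 and -0.01. Without WT 1 and WT 2 both calls were lost (-0.13, camera adjusted p = 0.0781, and 0.01, 0.723), and that of the ATF4 list also without WT 2 alone (-0.11, 0.0531) or KO 2 alone (-0.17, 0.0602). The p53 call was also lost with quantile normalization (-0.19, camera adjusted p = 0.0584), the dim filter (-0.25, 0.134) and array weights (-0.24, 0.0717). The ATF4 call was also lost with quantile normalization (-0.13, 0.0951), the dim filter (-0.19, 0.149) and rank-based camera (-0.18, 0.0549). In the ATF4 list the member that passed was Cth, which makes cysteine, at 8.11 ± 0.26 in WT and 7.33 ± 0.15 in KO. The unfolded protein response of the endoplasmic reticulum (0.10, camera adjusted p = 0.35), immediate early and heat shock genes (0.12, 0.35), autophagy and mitophagy (-0.10, 0.175, with a median of 0.02) and the cytosolic ribosome (0.07, 0.191) were not called in the chosen setting. With array weights the last was called higher (0.11, 0.0423). Immediate early and heat shock genes were called higher in KO without WT 3 (0.28, camera adjusted p = 0.0105) and with array weights (0.23, 0.0228). They were called lower without WT 1 and WT 2 (-0.21, 7.2e-05; adjusted p = 0.459 with an estimated correlation). Without WT 1 alone the test turned down uncalled (mean 0.03, 0.871).

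The list of cDC1 identity was higher in KO in the chosen setting, a call that rested on the arrays labelled WT 1 and WT 2. It had a mean of 0.91, with 40 of 44 members higher and 0 past adjusted over the list alone (camera adjusted p = 7.89e-06; adjusted p = 0.517 with an estimated correlation). Its mean relative to the KO mean was -0.65 on the array labelled WT 1, -2.09 on WT 2 and 0.00 on WT 3. Without WT 1 and WT 2 the call was lost (0.00, camera adjusted p = 0.815). Clec9a, the receptor of cDC1 for dead cells, read 10.46, 7.29 and 12.10 on WT 1 to 3 and 12.07 ± 0.03 (SD, n = 4) in KO. Lists of antigen presentation were not called in the chosen setting: the MHC class II pathway had a mean of 0.24 (13 of 16 higher, camera adjusted p = 0.136) and the MHC class I pathway with cross-presentation 0.15 (20 of 29 higher, 0.35). The former was called higher without WT 3 (0.35, 0.0345) and with array weights (0.31, 0.0392). With an estimated correlation 0 lists were called in either setting. Ciita, the master regulator of MHC class II genes, read 10.66, 10.48 and 11.46 on WT 1 to 3 and 11.65 ± 0.05 (SD, n = 4) in KO.

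Among markers of other cells, the monocyte and macrophage list was lower in KO by a mean of -0.27 (21 of 35 lower, camera adjusted p = 0.0303; adjusted p = 0.528 with an estimated correlation). Its list means were -0.31, 0.78 and 0.33 on WT 1 to 3. That call was lost without WT 2 (-0.01, camera adjusted p = 0.362), without WT 3 (-0.24, 0.434) and without KO 2 (-0.15, 0.153). It was lost too with the dim filter (-0.30, 0.0873), rank-based camera (-0.27, 0.056) and array weights, where the sign of the mean changed (0.05, 0.922). It was kept without WT 1 and WT 2 (-0.33, camera adjusted p = 4.15e-06; adjusted p = 0.459 with an estimated correlation). Mertk, a receptor for dying cells, read 10.07, 10.67 and 7.76 on WT 1 to 3 and 6.65 ± 0.50 (SD, n = 4) in KO. The list of cDC2 markers was not called in the chosen setting (mean -0.33, median -0.06, 4 past adjusted over the list alone, camera adjusted p = 0.0633), and stood at -0.22, 0.87 and 0.34 on WT 1 to 3. It was called lower in KO without WT 1 (-0.61, camera adjusted p = 0.000199), without KO 4 (-0.39, 0.0228) and without WT 1 and WT 2 together (-0.34, 2.44e-06; adjusted p = 0.459 with an estimated correlation). It was also called lower after median centring (-0.27, 0.0175) and with the replicate block (-0.39, 0.0472). Granulocyte and mast cell markers were higher in KO by a mean of 0.28 (25 of 29 higher, 2 past adjusted over the list alone, camera adjusted p = 0.00399; adjusted p = 0.469 with an estimated correlation). Those 2 members were the neutrophil granule gene Ngp, at 6.39 ± 0.08 (SD, n = 3) in WT and 7.72 ± 0.60 (SD, n = 4) in KO, and Stfa3, at 5.49 ± 0.09 and 5.90 ± 0.08. Stfa3 lay below the negative control median of 6.19 to 6.88 on every array, and Ngp in WT lay at the WT mean of those medians, 6.39, which was 6.73 in KO. Erythroid and platelet markers were higher by a mean of 0.23 (17 of 22 higher, 0 past adjusted over the list alone, camera adjusted p = 0.0292; adjusted p = 0.469 with an estimated correlation). On WT 1 to 3 the granulocyte list stood at -0.36, -0.39 and -0.08 and the erythroid list at -0.35, -0.29 and -0.06. Without WT 1 and WT 2 both calls were lost (0.08, camera adjusted p = 0.311, and 0.06, 0.545), and that of the erythroid list also without WT 1 alone (0.17, 0.0691) or KO 3 alone (0.18, 0.108). The erythroid call was lost too after median centring (0.29, 0.0545) and with the dim filter (0.14, 0.0937). The granulocyte list kept too few members with that filter to be tested. Lists of B and plasma cells (0.30, camera adjusted p = 0.181), plasmacytoid dendritic cells (0.05, 0.532) and T and NK cells (0.02, 0.447) were not called in the chosen setting. For the latter pair in the chosen setting camera's direction was down while mean and median were above 0. Without WT 1 and WT 2 that pair was called lower in KO (-0.29, 1.75e-05, and -0.39, 4.15e-06; adjusted p = 0.459 and 0.549 with an estimated correlation). Without WT 3 alone it turned upward uncalled (0.21, 0.359, and 0.22, 0.406), as it did without KO 2 alone (0.10, 0.928, and 0.18, 0.435). The B and plasma cell list was called higher without WT 3 (0.52, 0.0221) or without KO 2 (0.37, 0.0461), and in neither setting with an estimated correlation. The array labelled WT 3 alone stood 0.39 above the KO mean in the T and NK list, and the array labelled WT 1 stood -0.31 from it.

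**Figure D3:**
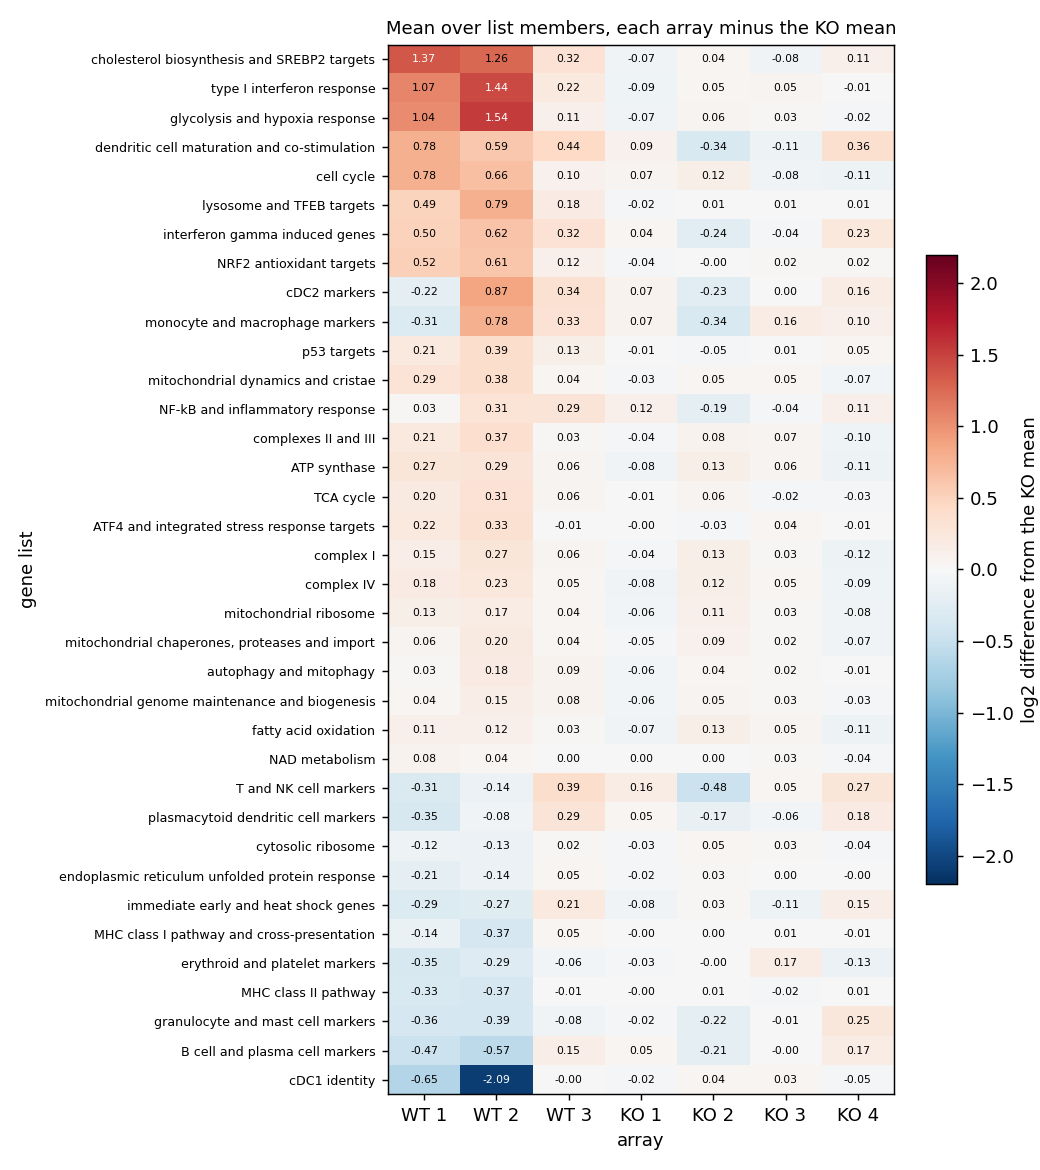
Mean log2 value over the members of each of 36 gene lists (rows) on each array (columns), minus the KO mean; colour gives the log2 difference, and lists are ordered by KO minus WT. The array labelled WT 2 stood at 1.54 for glycolysis and hypoxia and at -2.09 for cDC1 identity, where WT 3 stood at 0.11 and 0.00.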

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

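Of the tests here, those of the arrays labelled WT 1 and WT 2, of WT 3 against the KO arrays, and of other splits for genes past the adjusted threshold were chosen after the result was seen.

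Among the 4 KO arrays, 165 genes and 36 list means were examined for a value far from the other 3, and 9 of these 201 stood apart, where chance gives about 10. Cox11 was 9.87 on KO 2 against 9.53 to 9.57 (others). Fcmr was 9.04 on KO 2 against 9.27 to 9.28, and the mean of the TCA cycle list was 10.18 there against 10.09 to 10.10. On KO 4, Timm17a was 10.12 against 10.33 to 10.36, Il1b 12.97 against 12.68 to 12.71 and Fcrl1 9.98 against 10.43 to 10.47. Ern1 was 10.38 on KO 1 against 10.26 to 10.28, and the mean of the lysosome list was 10.33 there against 10.36 on the others. Paqr5 was 7.77 on KO 3 against 8.01 to 8.05.

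The negative control probe sets, which no comparison uses, had a KO mean of array medians of 6.73 ± 0.185 (SD, n = 4), above the WT mean of 6.39 ± 0.28 (SD, n = 3; exact two-sided permutation p = 0.171). The WT arrays read 6.19, 6.26 and 6.71. Background probe sets grouped by GC content showed no such shift, with medians of 5.56 to 5.62 on the 7 arrays.

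The arrays labelled WT 1 and WT 2 stood apart from the other 5 by melanocyte genes and by genes of spleen cDC1. Array scaling was examined by a further quantile normalization. The median of the melanocyte list then still lay 3.77 above the KO mean on WT 1 (95% bootstrap interval over genes 3.16 to 4.7). On WT 2 it lay 4.17 above (3.49 to 4.81). RMA already includes that step, so it could change little (3.78 and 4.21 before), and the test does not decide on array scaling. Melanoma cells mixed into spleen cDC1 alone would dilute leukocyte genes alike. On WT 1 the spleen resident genes lay 2.14 further below the KO mean than the shared cDC1 markers (1.39 to 3.38). On WT 2 they lay 3.59 further below than the pan-leukocyte genes (2.4 to 4.62). A first choice of test for WT 2, pan-leukocyte genes against shared cDC1 markers, gave 1.59 with an interval of 0.925 to 2.41, which decided nothing. These lists were written after values had been seen, and the intervals resample genes on 1 array. Other leukocytes could keep pan-leukocyte genes high on WT 2, where cDC2 markers stood at 0.87 and monocyte and macrophage markers at 0.78. The gaps are not those of plain dilution of spleen cDC1, but they cannot tell whether melanoma cells are present. For WT 1, cDC1 of another tissue carrying melanocyte RNA is a candidate explanation, as the shared cDC1 markers had a median only 0.397 below the KO mean (-0.397, interval -0.662 to -0.361), while for WT 2 that median was -1.94 (-2.73 to -1.35), beyond the fall of 1 log2 that the test allowed. Which cells WT 2 holds and whether a label is wrong stay open and untested. The growth protocol names tumor sorts and cDC2 beside splenic cDC1. Biological causes such as tumor antigen uptake by WT cells are untested too. Added melanocyte RNA alone would not lower the spleen resident genes, which had medians of -2.54 on WT 1 and -3.94 on WT 2. The members closest to the KO mean stood at -1.81 and -2.66, while the median on WT 3 was 0.09. These values argue against uptake alone for WT 1 and WT 2. For the melanocyte genes on WT 3 it stays open. A sort for cDC1 is meant to remove melanoma cells, but its purity was not examined here.

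At the adjusted threshold all 35 splits of the 7 arrays into 3 and 4 gave as many genes as the labelled one, as each gave 0. At an unadjusted p under 0.05, 2 of 35 splits gave at least 3820 genes, so chance is not excluded; the highest other split gave 4051 genes and joined WT 1, WT 2 and KO 2, and the 4 other splits that hold both WT 1 and WT 2 gave 2993 to 4051, which points to a structure of the arrays. For lists called by camera, 1 of 35 splits, the labelled one itself (23), gave as many. That share of 0.0286 is under 0.05 but is the smallest that 35 splits allow. The highest other split, KO 1, KO 2 and KO 4 against the rest, gave 22, and 4 more gave 21. The count of 23 thus lies close to what other splits give, and with an estimated correlation 0 lists were called. Chance is not excluded by that count.

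In the lists lower in KO than in WT 3 alone, an array's own deviation may account for the count, since 2 of the 4 KO arrays, each set alone against WT 3 and the other KO arrays, gave as many called lists as WT 3. WT 3 gave 14 lists, all higher on it, while KO 1 gave 9, all lower, KO 2 gave 6 higher and 9 lower, KO 3 gave 1 and 5, and KO 4 gave 7 and 8, so no KO array matched the single direction upward, which that test does not explain. The lists higher on WT 3 included dendritic cell maturation (0.44 above the KO mean), NF-kB and inflammation (0.29), cholesterol biosynthesis (0.32) and type I interferon (0.22), but also markers of T and NK cells (0.39), cDC2 (0.34), monocytes and macrophages (0.33) and plasmacytoid cells (0.29), and the melanocyte list, not among those tested, stood at 0.92. With an estimated correlation adjusted p was 0.549 for T and NK cells and 0.459 for the other 7. No biological explanation was tested beyond the labelled groups.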

How the results depend on the processing

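Leaving out WT 1 and WT 2 together, the melanocyte covariate and the estimated correlation within other alternatives were chosen after the data had been seen. Leaving out 1 array at a time gave 0 to 4931 genes, 20 to 24 lists and an Opa1 difference of -1.50 to -0.996; only without WT 3 did any gene pass (4931), where both remaining WT arrays carry the melanocyte signal, and the Opa1 adjusted p was then 0.0764. Array weights, which gave WT 3 0.241, WT 2 0.56 and WT 1 1.95, let 4458 genes pass. Over the other alternatives 0 genes passed, by Welch's test too (smallest adjusted p 0.565), and Opa1 stayed lower in KO and under no alternative passed, with adjusted p from 0.0764 to 0.813; the dim filter dropped Opa1, so it gave no value. The count at an unadjusted p under 0.05 (3820) was 1348 by Welch's test, 7189 without WT 3, 1616 without WT 2, 2230 without WT 1, 2449 without KO 1, 2283 with the dim filter, 7038 with array weights, 1154 without WT 1 and WT 2 and 1327 with the covariate. Lists numbered 23 in the chosen setting, 14 with the dim filter, 14 without WT 1 and WT 2, 14 with the covariate, and 0 with an estimated correlation, alone or with any of 16 other alternatives, and 0 with fry; the cause was not tested.

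Deviations of same-numbered arrays from their group means correlated at -0.04 to 0.05, and 0 of 3 WT arrays correlated best with its own number. The split of WT 1 and WT 2 from WT 3 dominates the WT deviations and could hide a shared litter or day. Pairing by replicate number was therefore not seen, but it is not excluded. With the replicate block, whether KO 4 was left out or its own block, 0 genes passed (2488 at an unadjusted p under 0.05), 24 lists were called and the Opa1 difference was -1.48.

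Directions of lists follow camera's test, so a mean can keep its sign where the direction turned. Leaving out 1 array turned immediate early and heat shock genes (means 0.0299 to 0.28), plasmacytoid markers (-0.11 to 0.21) and T and NK markers (-0.13 to 0.22). Quantile normalization turned mitochondrial genome maintenance and biogenesis (-0.0248), array weights turned it (-0.0568), plasmacytoid markers (0.23) and T and NK markers (0.21), the dim filter turned NAD metabolism (0.0709), plasmacytoid markers (0.13) and T and NK markers (0.00535), and fry turned plasmacytoid markers (0.0456). Without WT 1 and WT 2 the lists that turned had means of endoplasmic reticulum unfolded protein response -0.0483, immediate early and heat shock genes -0.21, cytosolic ribosome -0.0238, MHC class I pathway and cross-presentation -0.045, MHC class II pathway 0.0139, cDC1 identity 0.00319 and B cell and plasma cell markers -0.15, and the genes had Dnajb11 -0.17, H2-M3 -0.0144, Clec9a -0.0269, H2-Oa -0.0229, Cd8a -0.11, Fcrl1 -0.14, Klrb1c -0.0929 and Cxcr2 -0.0339. With the covariate, which nearly follows WT 1 and WT 2 so that its differences are extrapolated, the means of the 8 mitochondrial lists called lower all changed sign (0.00471 to 0.0756), and by camera's direction 16 of 36 lists turned, with means of complexes II and III 0.0756, mitochondrial dynamics and cristae 0.0621, fatty acid oxidation 0.0177, ATF4 and integrated stress response targets 0.10, endoplasmic reticulum unfolded protein response -0.11, glycolysis and hypoxia response 0.29, immediate early and heat shock genes -0.40, cell cycle 0.11, cytosolic ribosome -0.0652, MHC class I pathway and cross-presentation -0.16, MHC class II pathway -0.10, type I interferon response 0.12, cDC1 identity -0.55, B cell and plasma cell markers -0.39, granulocyte and mast cell markers -0.0634 and erythroid and platelet markers -0.00323, and 4 of its 14 lists were called in the same direction as in the chosen setting; glycolysis and hypoxia was called higher and cDC1 identity lower, opposite to that setting. Of 165 named genes 58 turned: Ndufv3 0.20, Uqcc2 0.14, Cyc1 0.24, Cox11 0.16, Atp5k 0.12, Atpaf1 0.17, Atp5g3 0.0747, Chchd10 0.52, Chchd6 0.13, Ogdh 0.0573, Pcx 0.13, Ppargc1a 0.57, Polg2 -0.46, Mgme1 0.0513, Ppargc1b 0.16, Timm17a 0.0306, Hadh 0.26, Eci1 0.12, Ero1a 0.0771, Creld2 -0.12, Ern1 -0.0454, Dnajb11 -0.41, Me1 0.54, Gpx4 0.33, Higd1a 0.0935, Tpi1 0.25, Aldh1l1 0.44, Nadk2 -0.26, Mitf 0.20, Tecpr1 0.41, Ei24 0.0544, Fos -0.12, Ier5 -0.19, Rpl11 -0.0638, Rpl23 -0.0852, Rplp0 -0.0713, Rpl14 -0.0496, Rab27a 0.45, Tap2 -0.21, H2-M3 -0.36, Clec9a -1.31, Ciita -0.10, Marchf1 -0.34, Lgmn 0.28, H2-Oa -0.35, Ifi27 0.12, Ifi27l2a 0.0703, Hacd1 0.50, Cd8a -1.61, Bst2 0.11, Paqr5 -0.0387, Ctsl 0.17, Sdc1 0.46, Fcrl1 -0.60, Lef1 -0.0305, Klrb1c -1.04, Cxcr2 -0.26 and Prtn3 -0.00389. The cause was not tested. Signal over background limits dim genes. Negative controls, some of them bright, had medians of 6.19 to 6.88, and background probe sets grouped by GC content 5.56 to 5.62.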

Other observations

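Genes of tissue-resident and stromal cells were read on the arrays after some values had been seen, and the tests of these lists were chosen after that. Of 8 genes of spleen resident CD8a cDC1, 8 had a higher mean in KO, and the list lay at a median of -2.54 from the KO mean on the array labelled WT 1, -3.94 on WT 2 and 0.09 on WT 3. Treml4, a receptor of splenic CD8a cDC1, read 9.37, 8.15 and 12.19 on WT 1 to 3 and 12.04 to 12.28 on the KO arrays. Tlr11, a sensor of profilin, read 9.01, 6.20 and 10.94 on WT 1 to 3 and 10.79 to 11.12 on the KO arrays. Dnase1l3, a secreted nuclease, read 8.29, 6.72 and 11.86 on WT 1 to 3.

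Of the 20 pan-leukocyte genes 17 had a higher mean in KO, with medians of -0.26, -0.35 and -0.02 on WT 1 to 3, and Spi1, the transcription factor PU.1, read 12.83, 12.82 and 12.89 on them. Of 14 fibroblast and endothelial markers 8 were higher and 6 lower in KO, with medians of -0.16, 0.10 and -0.04 on WT 1 to 3. Col1a1 read 9.12, 9.38 and 9.15 on WT 1 to 3. Kdr, an endothelial receptor for VEGF, read 10.07 and 10.97 on the arrays labelled WT 1 and WT 2 and 8.49 on WT 3, while Pecam1 read 7.95, 8.33 and 10.11. All 12 shared cDC1 markers had a higher mean in KO; all 12 also stand in the fixed lists, as do 4 of the 8 spleen resident genes and 2 of the 26 melanocyte genes.

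Melanocyte genes also differed between WT 3 and the KO arrays, and among the latter. Pmel read 11.62 on WT 3 and 9.75, 9.68, 9.11 and 7.99 on KO 1 to 4, and Dct 10.72 on WT 3 and 8.89, 8.45, 8.22 and 7.58. Sox10, a transcription factor of the melanocyte lineage, read 8.17 on WT 3 and 7.51, 7.10, 6.99 and 7.11 on KO 1 to 4. No explanation of these values was tested.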
